A study of Mus musculus with 9 samples.

How the data were processed

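Gene expression was measured by RNA sequencing in mouse embryonic stem cells (ESCs) homozygous for the iMOS T1-Myc allele, a construct that yields cells with different numbers of extra Myc copies marked by the yellow fluorescent protein EYFP. The cells also carried RERT, which makes recombination depend on 4-hydroxytamoxifen. Per the labels, ESCs were grown on gelatin-coated plates with LIF, and cultures were treated with 20 µM 4-hydroxytamoxifen for 24 h. Cells were sorted by EYFP level 24 h after removal of the drug, into cells with 2 extra copies of Myc and cells with no extra copy. Uninduced cultures of the same line were sorted as a control. The labels repeat the treatment text for the uninduced samples, and the titles and the design text were taken as the statement of their group. The design text calls the 3 samples of each group biological replicas; the labels do not say whether these are separate cultures. Total RNA was purified and sequenced as single-end reads of 75 bp, per the labels.

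The deposited table holds expected counts per gene, estimated by the authors with RSEM 1.17, per the file headers and the submitters' processing notes. The notes also name cutadapt, Picard and limma without a role. Reads were assigned to genes of GRCm38, annotation release 84 in the column names; the aligner is not given in the sources used here. The table had 35771 rows and 9 libraries, and the column names matched the sample labels. Expected counts divide reads that fit several genes, so close copies can share reads. Gene symbols, coordinates, transcript lengths and GC content came from GENCODE M21, also on GRCm38, in which 35432 of the 35771 identifiers had a name. No mitochondrially encoded gene had a count in any library.

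The totals per library ran from 4165286 to 8872303 rounded expected counts. Counts were rounded to whole numbers. The filter of edgeR (filterByExpr, by group) left 13424 genes, which held 99.8% of all counts. Levels are given as counts scaled to a common library total (CPM) computed here after TMM scaling, as mean ± SD over 3 libraries. Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit) in R 4.3.3, with all 9 libraries and 1 coefficient per group, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. Every adjusted p for a gene comes from this test unless another is named. Standard errors of log2 changes are the absolute change divided by the square root of F. The common biological coefficient of variation was 0.0394. The library numbers were tested as a block only as an alternative. Single genes of the Myc family also had a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

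Before the data were examined, the groups, the tests, most alternatives, 23 gene lists and the rule for named genes were fixed. The lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, two-sided, adjusted over the 23 lists per comparison. The test was repeated with an estimated correlation and with fry. The lists were Myc network, ribosome biogenesis, nucleotide, one-carbon and polyamine synthesis, cytosolic ribosomal proteins, glycolysis, oxidative phosphorylation, core pluripotency, naive pluripotency, formative and primed pluripotency, primitive streak and mesendoderm, neuroectoderm, extraembryonic endoderm, trophectoderm, two-cell-like state, fibroblast feeder, p53 targets, apoptosis machinery, integrated stress and unfolded protein response, DNA replication and G1/S, mitosis, cholesterol synthesis, FGF/ERK feedback, and immediate early and heat shock genes. Another 7 lists were chosen after seeing the data and are given only among the additional observations.

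The genes named per comparison were the 10 with the largest rise and the 10 with the largest fall among called genes. They needed a mean of at least 10 CPM, a proper gene symbol and no overlap between the 3 libraries of each group. Myc and Mycn were named in every comparison. From each list described, up to 2 members per direction with the smallest p could be named. The genes plotted per library were picked from these after their values were seen. Sequences of the named genes were compared with all annotated transcripts by minimap2 2.31-r1302. Another transcript with at least 95% identity over at least 50% of the gene's transcript marked it as uncertain. This held for Ahcy, Dppa3, Dppa5a, Hspa1a, Igf2, Ldha, Nme2, Npm1, Pgk1, Phgdh, Rplp0, Rps4x, Zscan4c, Zscan4d and Zscan4f. No source used here says that counting used strand. Exons of a tested gene on the other strand covered 67.3% of the exonic bases of Gins2, 57.2% of Fosl1, 43.5% of Gbx2, 29.9% of Ydjc, 24.3% of Rpl5, 23.4% of Ccnd1 and 17.7% of Bid. A tested gene on the same strand covered 48.9% of Nme2. The values of these genes are uncertain too.

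The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, unrounded counts, fits to 6 libraries, the replicate block, stricter thresholds and leaving out each library in turn. Removal of a smooth trend over transcript length and GC content was added after seeing the data. On simulated counts with 200 changed genes per comparison, the main test recovered 33.3% to 50.0% of 1.25-fold changes, 68.8% to 76.1% of 1.5-fold changes and 83.1% to 92.3% of 2-fold changes. False calls made up 9.22% of the calls for 2 extra copies against none, 7.79% for 2 extra copies against uninduced and 13.5% for no extra copy against uninduced, above the nominal 5%. These shares come from a single simulation per comparison and rest on 13, 12 and 21 false calls. Such shares depend on the number of changed genes, so they do not give the share of false calls in the data. Cells with 1 extra copy were not analysed here.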

Results

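The data were RNA-seq expected counts from 9 libraries of mouse ESCs of the iMOS T1-Myc line. There were 3 each from uninduced cells, cells with 2 extra copies of Myc and cells with no extra copy, all of them sorted. Myc is a transcription factor that drives growth and biosynthesis. Totals were 7070317, 7952695 and 6545308 counts for the uninduced libraries, 5762771, 5617097 and 7037890 with 2 extra copies, and 5826158, 8872303 and 4165286 with no extra copy. The cells with 2 extra copies and with no extra copy, called the induced populations, came from the same kind of induced mosaic culture. Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom of 1.36 to 2.89. Replicate 1 with 2 extra copies stood apart, at 2.55 and 2.89 against the other libraries of its group. Libraries and groups also differed in a trend over transcript length, with r of 0.247, 0.110 and 0.108 in uninduced libraries, 0.046, -0.229 and -0.274 with 2 extra copies, and -0.015, -0.0075 and 0.063 with no extra copy.

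The level of the manipulated gene was examined first. Myc (ENSMUSG00000022346; GRCm38 chromosome 15, 61985391 to 61990374) stood at 13.3 ± 1.51 CPM in uninduced cells, 31.6 ± 0.913 CPM with no extra copy and 142 ± 4.36 CPM with 2 extra copies (SD, n = 3 each). Cells with 2 extra copies had 4.52-fold more Myc than cells with none (log2 2.18, SE 0.066, adjusted p = 6.81e-23) and 10.7-fold more than uninduced cells (log2 3.42, SE 0.074, adjusted p = 1.88e-27). Cells with no extra copy had 2.36-fold more than uninduced cells (log2 1.24, SE 0.096, adjusted p = 1.10e-11). Mycn (ENSMUSG00000037169; chromosome 12, 12936093 to 12941914), a close relative of Myc, went the other way, with 188 ± 1.97 CPM in uninduced cells, 153 ± 2.89 with no extra copy and 126 ± 1.30 with 2 extra copies. Its adjusted p values were 3.34e-05, 5.20e-12 and 2.22e-06 for 2 extra copies against none, 2 extra copies against uninduced and none against uninduced. The two-sided exact permutation test gave p = 0.1 for both genes in each comparison, the smallest it can give. Gene counts do not separate endogenous from transgenic Myc transcripts.

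**Figure D1:**
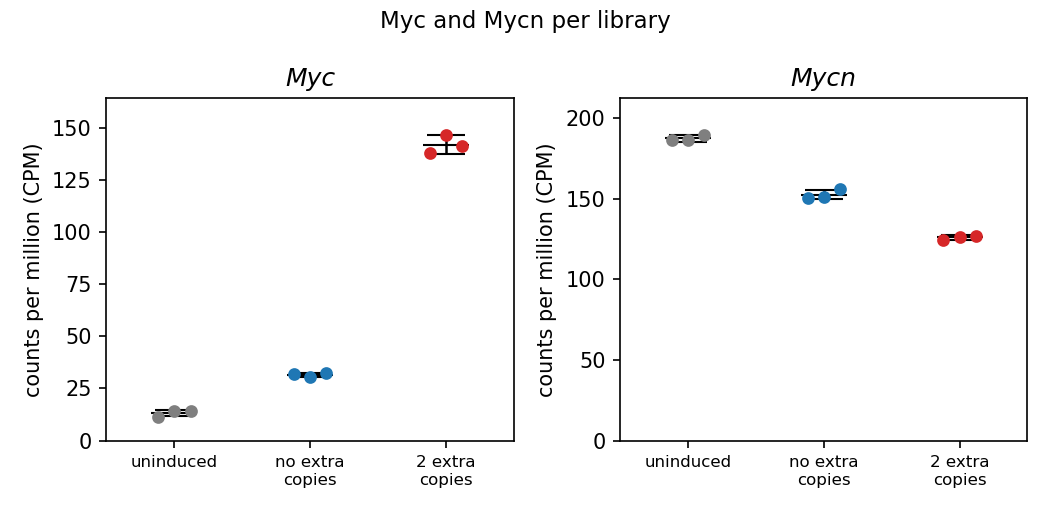
Myc and Mycn in CPM (vertical axes) in the 9 libraries by group, with a point per library and the mean and SD per group. Mean Myc is 13.3, 31.6 and 142 CPM in uninduced cells, cells with no extra copy and cells with 2 extra copies, while mean Mycn is 188, 153 and 126 CPM.

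Cells with 2 extra copies were compared with cells with no extra copy from the mosaic cultures, to find what differs with Myc dose between neighbouring cells. Ribosome biogenesis and mitosis genes were higher, and naive pluripotency and extraembryonic endoderm genes were lower, with 2 extra copies. Of the ribosome biogenesis list, 28 of 31 members were higher and 0 lower (30 and 0 adjusted over the list alone; adjusted p = 1.73e-26, and 0.0162 with an estimated correlation). Among these Ddx21, a nucleolar RNA helicase, rose 1.27-fold and Nolc1 1.26-fold. Of the mitosis list 13 of 16 members rose and 0 fell (the same adjusted over the list alone; adjusted p = 3.10e-13, and 0.00432 with an estimated correlation), with Ube2c at 1.34-fold and Top2a at 1.23-fold. Of the nucleotide, one-carbon and polyamine synthesis genes 18 of 22 rose and 0 fell (19 and 1 adjusted over the list alone; adjusted p = 2.00e-13). Spermidine synthase, Srm, rose 1.40-fold and Prps1 1.28-fold. That call is lost with an estimated correlation (adjusted p = 0.0610).

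Other lists also pointed up. Of the ribosomal protein genes 21 of 30 rose and 0 fell (22 and 0 adjusted over the list alone), with Rps4x at 1.11-fold; with library size alone in place of TMM, 12 rose. Of the glycolysis genes 8 rose and 2 fell of 19 (10 and 3 adjusted over the list alone). Lactate dehydrogenase A, Ldha, rose 1.56-fold, and the glucose transporters Slc2a1 and Slc2a3 were 1.24-fold and 1.13-fold lower. Of the oxidative phosphorylation genes 5 of 23 rose and 0 fell (9 and 0 adjusted over the list alone), with Uqcrc1 at 1.16-fold. The adjusted p values were 8.22e-13, 0.000627 and 0.000717, and all 3 calls are lost with an estimated correlation (adjusted p = 0.208, 0.292 and 0.165). The trend over transcript length also differed between these groups, and how much of these rises follows it is not given here. Of the two-cell-like list, genes of a rare ESC state that includes the Zscan4 family, 5 of 9 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 1.36e-05, but adjusted p = 0.130 with an estimated correlation), with Zscan4d at 1.59-fold. The Zscan4 genes of this list are close copies that can share reads, so its counts here and below may not rest on separate reads for each member. Of the p53 targets 5 of 20 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.00114, and 0.0426 with an estimated correlation), with Mdm2 at 1.22-fold and Trp53inp1 at 1.21-fold. With library size alone 3 p53 targets rose, 8 glycolysis genes rose and 3 fell, and 4 oxidative phosphorylation genes rose and 1 fell.

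Another 6 lists fell. Of the naive pluripotency list 8 of 17 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.000152, and 0.0426 with an estimated correlation). Gbx2 was 1.40-fold and Prdm14 1.84-fold lower, and Fbxo15 was 1.16-fold higher. Of the extraembryonic endoderm list 6 of 11 fell (7 and 1 adjusted over the list alone; adjusted p = 0.000186, and 0.0426 with an estimated correlation), with the matrix genes Sparc 1.65-fold and Col4a2 1.71-fold lower. Of the fibroblast list 5 of 9 fell and 0 rose (the same adjusted over the list alone; adjusted p = 6.14e-06, but adjusted p = 0.0610 with an estimated correlation), with smooth muscle actin Acta2 2.21-fold and Tagln 1.55-fold lower. Neuroectoderm genes fell in 5 of 7 (adjusted p = 0.0105), with Pax6 1.75-fold lower, and trophectoderm genes in 3 of 6 (adjusted p = 0.0165), with the keratins Krt8 and Krt18 1.48-fold and 1.49-fold lower; each had adjusted p = 0.130 with an estimated correlation and the same counts adjusted over the list alone. Core pluripotency genes fell in 4 of 12 (0 rose, adjusted p = 0.0105, but adjusted p = 0.208 with an estimated correlation; 4 and 0 adjusted over the list alone), with Nanog 1.19-fold and Pou5f1 1.10-fold lower; without replicate 1 of the cells with 2 extra copies the list had adjusted p = 0.157, and with library size alone 6 fell.

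The largest rises among named genes, beyond Myc, were Ahcy, which clears S-adenosylhomocysteine, at 1.70-fold, Ydjc at 1.68-fold, Zscan4d, Bspry and Mlxipl at 1.59-fold, Arhgdig at 1.58-fold, and Usp17la and Ldha at 1.56-fold. Necab2 rose 1.54-fold, and DESeq2 gave it an adjusted p of 0.0587. The largest falls among named genes were the growth factor Igf2 (chromosome 7, 142650766 to 142666816) at 3.03-fold and its imprinted neighbour H19 (chromosome 7, 142575529 to 142578143) at 2.39-fold. Next were Myl9 at 2.37-fold, Acta2 at 2.21-fold, AU015836 at 1.96-fold and Cntn2 at 1.90-fold. Then came Cplx2 at 1.88-fold, Nuak1 at 1.87-fold, Pcdh1 at 1.85-fold and Tcaf1 at 1.84-fold. Igf2 and Acta2 also ranked among the largest rises of named genes with no extra copy against uninduced, and the other falls listed here did not. In all, 2148 of 13424 genes (16.0%) were called, 1114 higher and 1034 lower, with a median absolute log2 change of 0.28. With library size alone in place of TMM, 774 were higher and 1360 lower, or 36.3% higher against 51.9%. Only 98 called genes changed at least 2-fold, 13 higher and 85 lower. The groups did not overlap in 30.6% of all genes, against 10% by chance. Without replicate 2 of the cells with no extra copy, the deepest library, 1397 genes were called, and DESeq2 called 936.

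**Figure D2:**
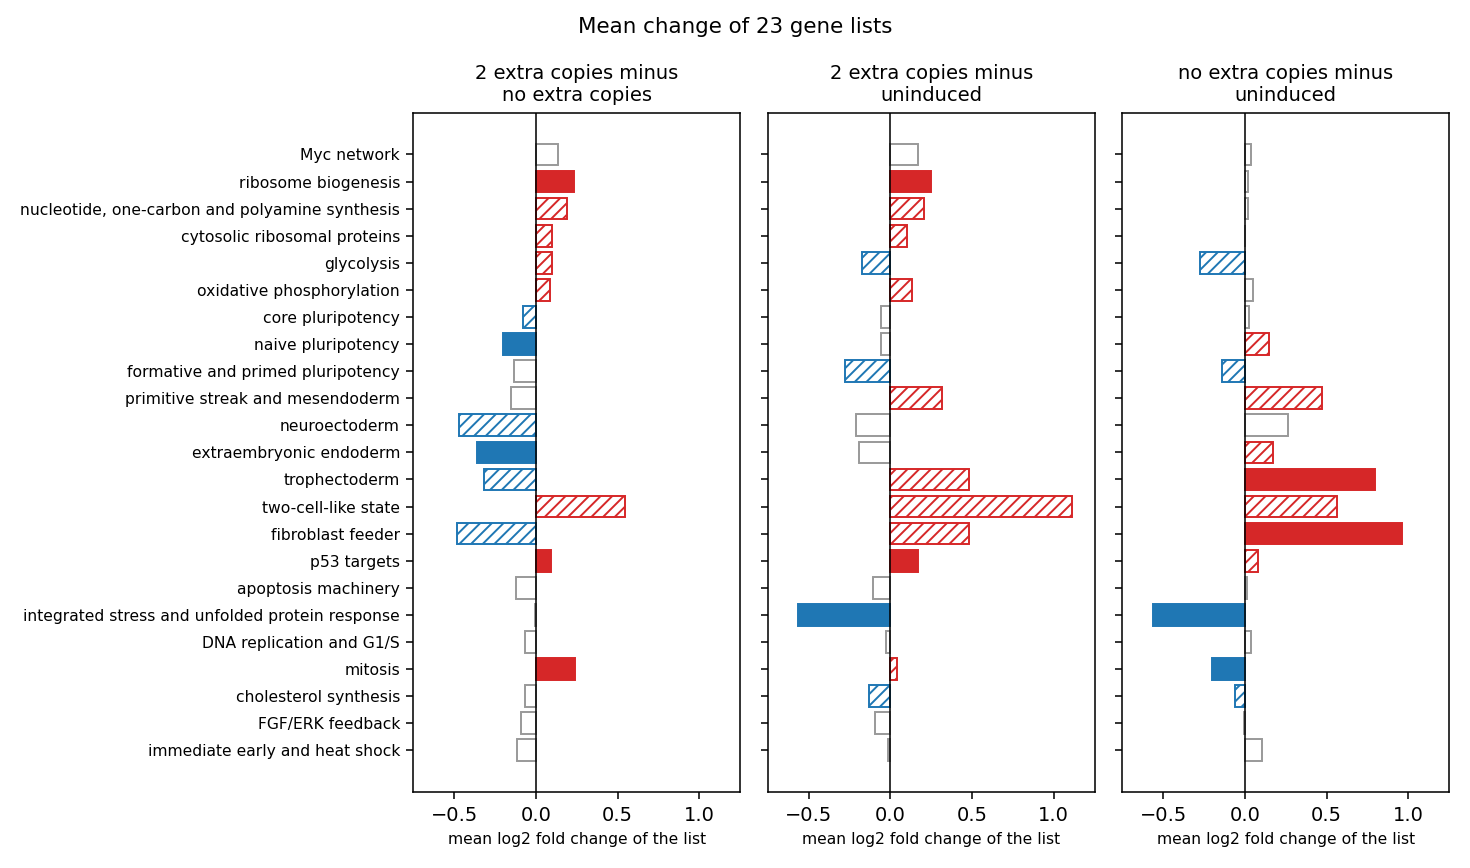
Mean log2 change (horizontal axis) of the 23 gene lists in the 3 comparisons. Filled bars passed an adjusted p of 0.05 with the preset and the estimated correlation, hatched bars with the preset one only, and white bars with neither; ribosome biogenesis is filled with 2 extra copies against none and against uninduced, and mitosis is filled red against none and filled blue for no extra copy against uninduced.

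Cells with 2 extra copies were then compared with uninduced cells, which takes in Myc dose together with the drug, recombination and culture beside other cells. Ribosome biogenesis rose again, in 29 of 31 members with 0 lower (the same adjusted over the list alone; adjusted p = 6.34e-21, and 0.0199 with an estimated correlation), with Polr1b at 1.35-fold and Nhp2 at 1.28-fold. p53 targets rose in 12 of 20 with 0 lower (12 and 1 adjusted over the list alone; adjusted p = 5.15e-06, and 0.0199 with an estimated correlation), with Plk2 at 1.40-fold and Mdm2 at 1.36-fold. Genes of the integrated stress and unfolded protein response fell in 15 of 19 with 0 higher (the same adjusted over the list alone; adjusted p = 3.76e-13, and 0.0199 with an estimated correlation), with the glutathione-degrading enzyme Chac1 2.30-fold and asparagine synthetase Asns 1.49-fold lower. Those 3 lists kept their call with an estimated correlation.

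Another 11 lists passed with the preset correlation only. Nucleotide, one-carbon and polyamine genes rose in 16 and fell in 2 of 22 (adjusted p = 1.14e-09; Srm 1.52-fold and Shmt1 1.35-fold higher), ribosomal proteins rose in 17 and fell in 0 of 30 (adjusted p = 8.83e-10), and oxidative phosphorylation genes rose in 12 and fell in 1 of 23 (adjusted p = 2.56e-05; Sdhd 1.31-fold higher). With an estimated correlation their adjusted p was 0.0924, 0.285 and 0.102. The mean log2 change of the ribosomal protein list was only 0.099. The trend over transcript length had log2 slopes per doubling of 0.054, 0.022 and 0.023 in the uninduced libraries. With 2 extra copies the slopes were 0.0098, -0.055 and -0.062. How much of these small rises follows that trend is not given here. Two-cell-like genes rose in 8 and fell in 0 of 9 (adjusted p = 2.12e-08, but adjusted p = 0.0924 with an estimated correlation), with Usp17le at 2.28-fold and Zscan4d at 2.11-fold. Trophectoderm genes rose in 2 of 6 (adjusted p = 0.00630; Krt18 2.00-fold, Krt8 1.85-fold) and primitive streak genes in 4 of 7 (adjusted p = 0.0128; Lefty1 1.35-fold), both with 0 lower and adjusted p = 0.0924 with an estimated correlation. Without uninduced replicate 3 the primitive streak list had adjusted p = 0.0539. Fibroblast-list genes rose in 6 and fell in 0 of 9 (adjusted p = 0.000817, but adjusted p = 0.111 with an estimated correlation), with Col1a2 at 1.99-fold and Tagln at 1.56-fold.

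Glycolysis genes fell in 10 and rose in 3 of 19 (adjusted p = 0.00120, but adjusted p = 0.356 with an estimated correlation), with Slc2a1 1.88-fold and Pfkp 1.42-fold lower and Slc16a1 1.19-fold higher. Formative and primed pluripotency genes fell in 8 and rose in 1 of 16 (adjusted p = 0.00190, but adjusted p = 0.0688 with an estimated correlation), with Lef1 2.40-fold and Zic2 1.76-fold lower. Cholesterol synthesis genes fell in 9 and rose in 0 of 20 (adjusted p = 0.00189, but adjusted p = 0.0924 with an estimated correlation), with Msmo1 1.29-fold lower. Mitosis genes rose in 6 and fell in 1 of 16 (adjusted p = 0.0478, but adjusted p = 0.111 with an estimated correlation). The mitosis call was also lost without uninduced replicate 2 (0.0628), uninduced replicate 3 (0.0544), replicate 1 with 2 extra copies (0.1001) and replicate 2 with no extra copy (0.0522). Adjusted over the list alone, the counts higher and lower were 17 and 2 for nucleotide synthesis, 20 and 0 for ribosomal proteins, 14 and 1 for oxidative phosphorylation, 4 and 10 for glycolysis, 2 and 9 for formative genes and 6 and 2 for mitosis, and as given for the other 5 lists.

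Only genes that met the rule for named genes, with a mean of at least 10 CPM, are ranked in this paragraph. The genes with the largest rises were Myc, Usp17la at 2.45-fold, Cbr3 at 2.39-fold, Usp17le and Zscan4d. Next were Anxa1 at 2.00-fold, Krt18, Zscan4c at 1.99-fold, Col1a2, and Zscan4f at 1.94-fold. The largest falls were Bnip3 at 3.17-fold, Egln3 at 3.02-fold and Ndrg1 at 2.91-fold, all known as hypoxia-responsive, then the stress factor Ddit3 at 2.85-fold, Lef1, Ccng2 at 2.33-fold, Chac1, Ddit4 at 2.28-fold, Srrm4 at 2.26-fold and Lrp2 at 2.16-fold. Lrp2 had adjusted p = 0.0144, which became 0.0513 without uninduced replicate 1 and 0.0539 without replicate 2 with 2 extra copies. In all, 3350 of 13424 genes were called, 1721 higher and 1629 lower. The larger direction depends on scaling, with 1494 higher and 1848 lower with library size alone and 1589 and 1765 with upper-quartile factors. At least 2-fold changes were seen in 199, 76 higher and 123 lower. The groups did not overlap in 38.5% of all genes, against 10% by chance. DESeq2 called 1628.

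Cells with no extra copy were compared with uninduced cells, which asks what differs in induced cultures in cells sorted as having no extra copy; their Myc level was 2.36-fold that of uninduced cells. Genes of the fibroblast and trophectoderm lists rose, and stress-response and mitosis genes fell. Of the fibroblast list 7 of 9 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 3.50e-11, and 0.0254 with an estimated correlation). The collagen gene Col1a2 rose 3.66-fold, from 9.99 ± 0.676 to 36.4 ± 2.38 CPM (SD, n = 3), and Tagln 2.41-fold. Of the trophectoderm list 4 of 6 rose and 0 fell (the same adjusted over the list alone; adjusted p = 1.11e-05, and 0.0254 with an estimated correlation), with Krt18 at 2.97-fold and Krt8 at 2.75-fold; both are general epithelial keratins. Stress-response genes fell in 14 of 19 with 0 higher (15 and 1 adjusted over the list alone; adjusted p = 6.95e-19, and 0.00707 with an estimated correlation), with Asns 1.63-fold and Psat1 1.53-fold lower. Mitosis genes fell in 11 of 16 with 0 higher (14 and 0 adjusted over the list alone; adjusted p = 1.20e-10, and 0.00707 with an estimated correlation), with Top2a 1.23-fold and Kif11 1.21-fold lower.

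Ribosome biogenesis was not past the threshold here, with 3 higher and 2 lower of 31 (4 and 2 adjusted over the list alone; adjusted p = 0.694). The remaining 8 calls were lost with an estimated correlation. Glycolysis genes fell in 13 and rose in 1 of 19 (adjusted p = 3.97e-14, but adjusted p = 0.0937 with an estimated correlation), with Pfkp 1.63-fold and Pgk1 1.43-fold lower. Naive pluripotency genes rose in 8 and fell in 2 of 17 (adjusted p = 0.00202, but adjusted p = 0.0684 with an estimated correlation), with Tbx3 at 1.46-fold and Fbxo15 1.18-fold lower. Two-cell-like genes rose in 4 of 9 with 0 lower (adjusted p = 0.000237, but adjusted p = 0.162 with an estimated correlation), with Zscan4d at 1.32-fold. p53 targets rose in 8 and fell in 2 of 20 (adjusted p = 0.0101, but adjusted p = 0.0726 with an estimated correlation), with Perp at 1.36-fold. Extraembryonic endoderm genes rose in 3 of 11 with 0 lower (adjusted p = 0.0393, but adjusted p = 0.144 with an estimated correlation), with Col4a2 at 1.75-fold; the list had 0.0502 without uninduced replicate 3 and 0.0571 without replicate 3 with no extra copy. Cholesterol synthesis genes fell in 4 of 20 with 0 higher (adjusted p = 0.0393, but adjusted p = 0.189 with an estimated correlation); the list had 0.0682 without uninduced replicate 1 and 0.0721 without uninduced replicate 3, and 6 fell with upper-quartile factors and 2 with library size alone.

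Formative and primed genes rose in 4 and fell in 6 of 16 (adjusted p = 0.0450, but adjusted p = 0.131 with an estimated correlation), with Lef1 2.69-fold and Otx2 1.82-fold lower and Etv4 1.30-fold higher. The call was lost without uninduced replicate 2 (0.0605) or 3 (0.0537), without replicate 3 with 2 extra copies (0.0543), and without replicate 1 (0.0751) or 3 (0.0604) with no extra copy. Primitive streak genes rose in 2 of 7 with 0 lower (adjusted p = 0.0211, but adjusted p = 0.0996 with an estimated correlation), and the list had 0.0721 without uninduced replicate 3. Adjusted over the list alone, 9 and 2 naive genes, 5 and 0 two-cell-like genes, 4 and 0 primitive streak genes and 0 and 7 cholesterol synthesis genes were higher and lower, and the other 4 of these 8 lists had the counts given.

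The rankings here hold among genes that met the rule for named genes, with a mean of at least 10 CPM. The largest rises were Col1a2, Krt18, Col1a1 at 2.81-fold, Acta2 at 2.75-fold and Krt8. Next were the annexin Anxa1 at 2.72-fold, Tagln, Igf2 at 2.39-fold, Myc and S100a6 at 2.26-fold. The largest falls were Ndrg1 at 3.01-fold, Bnip3 at 2.75-fold, Lef1, Egln3 at 2.68-fold, Stc2 at 2.40-fold, Mef2b at 2.27-fold, Ddit4 at 2.23-fold, Ubap1l at 2.20-fold, Chac1 at 2.14-fold and Ddit3 at 2.08-fold. In all, 1811 genes (13.5%) were called, 953 higher and 858 lower, and 93 changed at least 2-fold, 59 higher and 34 lower. Here too the split depends on scaling, with 1105 higher and 742 lower with library size alone and 868 and 953 with upper-quartile factors. The groups did not overlap in 31.5% of all genes, against 10% by chance. Without replicate 2 with no extra copy 1177 genes were called, and DESeq2 called 685.

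**Figure D3:**
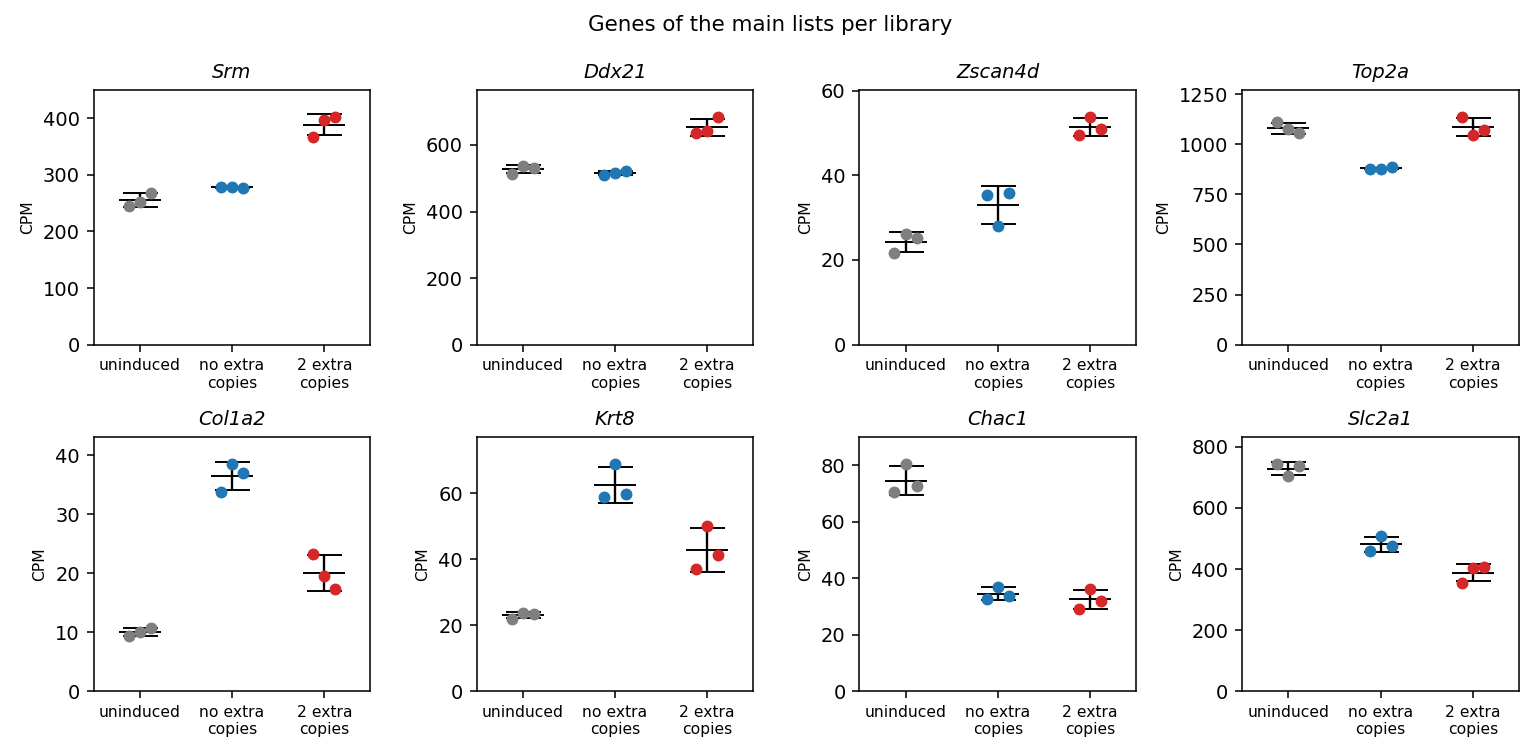
CPM (vertical axes) of Srm, Ddx21, Zscan4d, Top2a, Col1a2, Krt8, Chac1 and Slc2a1 in the 9 libraries by group, with a point per library and the mean and SD per group. Col1a2 and Krt8 are highest in cells with no extra copy, at 36.4 and 62.5 CPM, and Chac1 is highest in uninduced cells, at 74.6 CPM.

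The lists not past the threshold had these counts higher and lower. For 2 extra copies against none they were Myc network 3 and 1, formative and primed 1 and 5, primitive streak 2 and 1, apoptosis machinery 2 and 5, stress response 3 and 2, DNA replication and G1/S 2 and 8, cholesterol synthesis 1 and 2, FGF/ERK feedback 0 and 1, and immediate early and heat shock 1 and 2. Adjusted over the list alone these became 3 and 2, 3 and 6, 2 and 1, 3 and 5, 3 and 3, 2 and 9, 1 and 2, 0 and 1, and 1 and 2. For 2 extra copies against uninduced they were Myc network 3 and 2, core pluripotency 1 and 3, naive pluripotency 3 and 3, neuroectoderm 0 and 2, extraembryonic endoderm 0 and 4, apoptosis machinery 3 and 4, DNA replication 4 and 4, FGF/ERK feedback 0 and 2, and immediate early 2 and 0. Adjusted over the list alone these became 3 and 4, 1 and 4, 3 and 4, 0 and 3, 0 and 4, 3 and 4, 4 and 5, 0 and 2, and 2 and 0.

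For no extra copy against uninduced, the other lists not past the threshold were Myc network 1 and 1, nucleotide synthesis 5 and 3, ribosomal proteins 0 and 0, oxidative phosphorylation 5 and 1, core pluripotency 2 and 2, neuroectoderm 2 and 1, apoptosis machinery 1 and 2, DNA replication 5 and 2, FGF/ERK feedback 1 and 1, and immediate early 2 and 0. Adjusted over the list alone these became 1 and 1, 6 and 3, 0 and 0, 5 and 2, 2 and 3, 2 and 1, 2 and 3, 6 and 2, 2 and 1, and 2 and 0. For the 30 ribosomal protein genes edgeR's quasi-likelihood test called 0 members, and with the length and GC trend removed camera called the list lower (adjusted p = 1.48e-04). Mean, median and test differed in sign for lists that did not pass, namely the Myc network in all 3 comparisons, primitive streak and stress response for 2 extra copies against none, apoptosis and immediate early genes for 2 extra copies against uninduced, and neuroectoderm and FGF/ERK feedback for no extra copy against uninduced. Under the 3 other scalings the mean changed sign in stress response for 2 extra copies against none (RLE factors) and in ribosomal proteins and FGF/ERK feedback for no extra copy against uninduced (library size alone), none of them called. Small counts moved with scaling as well. For 2 extra copies against none, DNA replication genes were lower in 4 rather than 8 with RLE factors, cholesterol synthesis genes were higher in 0 and lower in 5 with library size alone, and stress-response genes were then higher in 2 and lower in 3. For 2 extra copies against uninduced, core pluripotency genes were lower in 5 rather than 3 with library size alone, and DNA replication genes were lower in 2 rather than 4 with RLE factors. The Myc network there had 3 higher and 4 lower with upper-quartile factors and with library size alone. For no extra copy against uninduced, DNA replication genes were higher in 3 rather than 5 with upper-quartile factors, and apoptosis genes were higher in 2 and lower in 1 with library size alone.

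Both induced populations were compared for how they differed from uninduced cells. Across 13424 genes the log2 changes had r = 0.516, against a mean of 0.467 and a maximum of 0.517 in 20 simulations of unchanged groups against the same controls; genes are not independent replicates. This r is not above the largest simulated one, and it ran from 0.434 without replicate 3 with no extra copy to 0.607 without uninduced replicate 3, with 0.569 under the filter of 5 CPM. The covariance was 0.0539 against 0.0202 simulated, a difference of 0.0338. In both comparisons 475 genes were higher and 527 lower, against 122 and 104 for independent lists. The simulated groups held no change, so their shared calls, with means of 0.1 and 0.25, were few by design and do not gauge this overlap. Opposite calls were made for 47 genes, against 226 for independent lists. The 3 control libraries cannot be divided into 2 sets of 2, so part of the excess may come from the shared controls.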

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

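The fits with the length and GC trend removed were chosen after seeing the data; the other alternatives were planned. For 2 extra copies against none, 2 extra copies against uninduced and no extra copy against uninduced, the main counts of called genes were 2148, 3350 and 1811. DESeq2 called 936, 1628 and 685, of which 898, 1592 and 672 were also called by the main test; the cause was not tested. An adjusted p below 0.01 left 1179, 2058 and 1002, and a log2 change of at least 1 left 98, 199 and 93, by construction. Leaving out each library gave 1397 to 2564, 2453 to 3719 and 1177 to 2201, with the lowest values in the first and last without replicate 2 with no extra copy and the highest of each without replicate 1 with 2 extra copies. The other planned settings gave counts within 1.5 times the main ones, as did removal of the length and GC trend (2285, 3418 and 1838, of which 1847, 2810 and 1443 were shared). Lists past the threshold numbered 14, 14 and 12, and 5, 3 and 4 with an estimated correlation; the cause was not tested. The log2 change of Myc ran from 2.14 to 2.21, from 3.33 to 3.47 and from 1.151 to 1.29 over the settings run for single genes, namely RLE factors, library size alone, the replicate block, DESeq2, limma-voom, each library left out and the length and GC trend removed. Of 226 called named-gene results 178 kept their call in all of these. Of 40 called list results 12 kept theirs in all settings run for lists, namely estimated correlation, fry, the replicate block, the 5 CPM filter, each library left out and the trend removed. In these runs 0 results reversed. The replicate block gave 2233, 3440 and 1933 calls. Same-numbered libraries had correlations of deviations of -0.081 to 0.081 in 9 pairs, none over 0.1, and 3 of 9 libraries correlated best with their own number, so the numbers were not taken to pair samples. Depth limits small changes: 3 counts correspond to 0.338 to 0.720 CPM per library.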

Other observations

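The tests of carry-over in the sort, of feeder fibroblasts, of transcript length and GC content and of sampling error of the shared uninduced libraries, and the 7 lists described first, were chosen after the results were seen; the remaining tests here were written down before their values were read, though after they had been computed.

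Genes known to respond to hypoxia fell in both induced populations against uninduced cells. With no extra copy 16 of 24 were lower and 0 higher (camera adjusted p = 1.56e-14, and 0.0214 with an estimated correlation). Among them Vegfa was 1.94-fold lower. Adm was 5.59-fold lower, but at a low level, with 1.09 CPM in cells with no extra copy. With 2 extra copies 14 were lower and 1 higher (adjusted p = 2.21e-09, but adjusted p = 0.0568 with an estimated correlation). Members that had stood out before the list was made were then left out, and the rest are called unseen. Among the 19 unseen members 11 were lower with no extra copy (adjusted p = 1.59e-07). With 2 extra copies 9 were lower and 1 higher (adjusted p = 2.12e-04). Hk2, Pdk1 and Mxi1 among the 19 also belong to fixed lists tested before, and all values come from the same libraries. Between the induced populations the hypoxia list was not past the threshold (2 higher, 2 lower, adjusted p = 0.703). Contractile and adhesion genes rose in 22 of 24 members with no extra copy against uninduced (adjusted p = 1.55e-23, and 0.00236 with an estimated correlation), with Tpm1 at 1.57-fold, and fell in 21 with 2 extra copies against none (adjusted p = 4.13e-23, and 0.00214 with an estimated correlation). With 2 extra copies against uninduced 6 rose and 6 fell (adjusted p = 0.888). Keratin and annexin genes rose in 14 of 14 with no extra copy against uninduced (adjusted p = 2.62e-20, and 0.00495 with an estimated correlation), with Lgals1 at 1.79-fold. They fell in 13 with 2 extra copies against none (adjusted p = 4.10e-10, and 0.0182 with an estimated correlation) and rose in 7 against uninduced (adjusted p = 2.22e-05, but adjusted p = 0.0685 with an estimated correlation). That last call rests on the genes that prompted the list, since over its 8 unseen members 2 rose and adjusted p was 0.142. Over the same 8 members 8 rose with no extra copy against uninduced (adjusted p = 3.86e-10) and 8 fell with 2 extra copies against none (adjusted p = 6.74e-07).

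Imprinted genes fell in 13 and rose in 2 of 30 with 2 extra copies against none (adjusted p = 5.27e-09, and 0.00214 with an estimated correlation), with Peg10 1.49-fold and Cdkn1c 1.67-fold lower. Against uninduced, 11 fell and 4 rose with 2 extra copies (adjusted p = 5.49e-04, and 0.0337 with an estimated correlation), and 9 rose and 4 fell with none (adjusted p = 0.0329, but adjusted p = 0.0639 with an estimated correlation). Over the 23 unseen imprinted genes the adjusted p was 0.00122, 0.0360 and 0.747 in these 3 comparisons, so the last call rests on the genes that prompted the list. Mitochondrial translation and import genes rose in 13 of 22 with 2 extra copies against none and in 16 against uninduced, with 0 lower in each (with an estimated correlation adjusted p = 0.0182 and 0.0337), with Hspd1 at 1.19-fold and 1.32-fold; with no extra copy against uninduced 5 rose and 1 fell (adjusted p = 0.0206, but adjusted p = 0.225 with an estimated correlation, and 0.0564 over the 21 unseen members). Aminoacyl-tRNA synthetase genes fell in 13 and rose in 1 of 20 with no extra copy against uninduced (0.0349 with an estimated correlation), with Nars 1.35-fold lower. They rose in 11 with 0 lower with 2 extra copies against none (0.0307 with an estimated correlation), and 6 rose and 8 fell against uninduced (adjusted p = 0.291). Lysosome genes rose in 5 of 20 with no extra copy against uninduced (0.0489 with an estimated correlation), fell in 5 with 2 extra copies against none (adjusted p = 0.111 with an estimated correlation), and were not past the threshold with 2 extra copies against uninduced (3 higher, 4 lower, adjusted p = 0.370). Over unseen members the other calls of the contractile, mitochondrial and aminoacyl-tRNA synthetase lists stayed past the threshold, and no lysosome gene had to be left out. Adjusted p values of these lists are over the 7 lists per comparison, and unseen members were tested with the preset correlation only. These 7 lists were not run under the other alternatives.

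Myc was above the uninduced level in cells sorted as having no extra copy. The choice among the scalings tried does not account for it, since the lowest log2 change under the 3 other scalings was 1.23. Those scalings moved the median log2 change of all genes by only -0.011 to 0.015, so none of them could have removed a change of this size. Carry-over of cells with 2 extra copies may account for the raised Myc level. The Myc level would need a share of 14.2% of such cells, which predicts a mean log2 change of 0.038 in the ribosome biogenesis list. Carry-over of cells with 1 extra copy was not modelled, since they were not analysed here. The observed mean was 0.017 with a 95% interval of -0.014 to 0.048, which holds both 0 and the prediction. That interval treats the 31 genes as independent, and with their estimated correlation of 0.134 it is likely too narrow. Carry-over and a rise of Myc in these cells cannot be told apart.

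Fibroblast-list genes were higher with no extra copy than in uninduced cells, and the labels name no feeder cells. Feeder fibroblasts would bring their other abundant transcripts. In the list, 6 further genes together rose by 1.26% of the rise of Col1a1, Col1a2, Acta2 and Tagln (upper bound 3.12%). Of these, Col3a1 went from 2.45 to 4.32 CPM, the direction that feeders would give. Thy1 went from 4.99 to 4.09 CPM, and Dcn, Lum, Postn and S100a4 stayed under 1 CPM. List members Col5a1, Loxl1 and Vim were in neither sum, so the test covers part of the list and does not rule out feeders. For transcript length and GC content, the mean log2 change of the list was 0.96 before and 0.93 after the trend was removed, with 7 of 9 members still called. This test went through 3 forms, each set after the one before had been seen: a normal lower bound on the corrected mean (0.50, above the bar of 0.48, or 50% of the mean before), a t lower bound on it (0.42, below 0.48, which left the trend open), and a paired upper bound on the change taken away (0.060). The bounds on the corrected mean carry the spread between the 9 members, with an SE of 0.219 before and after correction. They therefore do not gauge how much of the rise the trend gave. The mean change taken away was 0.036, and its upper bound of 0.060 lies below 0.48. These values argue against the trend as the source of 50% or more of the rise of this list. A smaller part is not ruled out, feeders stay open, and no biological explanation is put forward.

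Stress-response genes were lower in both induced populations than in uninduced cells. With the length and GC trend removed, the weaker of the 2 mean log2 changes was -0.57. Leaving out each uninduced library in turn gave a weakest mean of -0.54, so no single one carries the pattern. For sampling error of the shared uninduced libraries, the weaker mean log2 difference of the list had an upper 95% bound of -0.47 from the spread between libraries of a group; this test replaced a count over all genes, which did not bear on this list. A biological difference between induced and uninduced cultures stays as a hypothesis, and the design does not separate the drug, recombination, growth beside cells with extra Myc and the culture itself.

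The 6 libraries of each comparison can be split in 10 ways, so no share under 0.05 can be reached. In fits to those 6 libraries, 1 split, the real one, gave the most calls in each comparison. The real split gave 1947 calls against 1 for the highest other with 2 extra copies against none, 3186 against 2 with 2 extra copies against uninduced, and 2142 against 1 with no extra copy against uninduced. Every other split puts libraries of both groups in each part, so any difference between the groups adds to the spread within the parts. Few calls then follow whatever the cause of the difference, and no conclusion is drawn from this contrast.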
